A study of Mus musculus with 6 samples.

How the data were processed

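Total RNA from mouse ovarian granulosa cells was labelled with biotin by an Affymetrix protocol and measured on 1 array per sample, per the labels. The deposited values are intensity per probe set on a linear scale, written as whole numbers. They were made with affy and RMA, per the submitters' processing notes; versions are not given, and the rounding and the return from the log2 scale used by RMA are not described in the sources used here. The genome build is likewise not given in the sources used here. The lowest value was 6 or 7 on every array and the upper quartile lay between 370 and 383, so the arrays share 1 distribution closely. RMA forces this likeness, so a change of most genes in 1 direction would not be seen.

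The values were transformed as log2(value + 1), and a fold is on that scale, which understates changes of dim genes. Of 45101 probe sets, 64 AFFX controls were left out and 45037 were fitted. The platform annotation gave 1 gene symbol for 34945 of these, several for 932 and none for 9160, and only probe sets with 1 symbol were named. Each of 18193 genes was represented by the probe set with the highest mean over all arrays, and 9010 genes had more than 1. Gene IDs were looked up in a RefSeq table of GRCm38.p6, used for names only, where 18032 of the 18193 genes matched and 0 symbols were updated.

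R 4.3.3 and limma 3.58.1 were used. A single fit of all 6 arrays held a mean per group, with 3 residual degrees of freedom, and gave 3 two-sided contrasts with empirical Bayes moderation. Adjusted p-values of genes are Benjamini-Hochberg values over the 45037 probe sets of a contrast, with a threshold of 0.05. Values per group are mean intensity ± SD of 2 arrays. Sample groups, tests, gene lists, named genes and most alternatives were chosen before the data were examined. The rule for named genes took up to 12 genes per direction that passed the threshold without overlap, and otherwise the 5 of smallest p in each direction, passing over unnamed transcripts. It added the FOXO, inhibin, activin, steroid and receptor genes of granulosa cells and up to 4 members of smallest p per list; not all of these are printed.

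The gene lists were 16 pathways and 8 sets of markers of other cell types, with 514 measured members counted with repeats. They were tested on the representative probe sets with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 24 lists. Camera with an estimated correlation and fry were the alternatives. With an estimated correlation 0 lists were called in any contrast, and fry called 0 for change in 1 direction, while its test of change in either direction passed 2 lists for dKO at day 25 against wild type, 3 between the dKO ages and 15 for dKO at 2 months against wild type. Some lists overlap, and several markers of other cells are also expressed in granulosa cells.

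On simulated data with the group sizes of the day 25 comparison and 45037 probe sets, 50 changed at each of 4 sizes, limma recovered 28% of 2-fold, 90% of 4-fold, 96% of 8-fold and 100% of 16-fold changes, with 8 false calls. Camera called 0 of 24 unshifted lists. The simulated noise was normal and independent between genes, so the camera result says nothing about genes that vary together. It had the moderated spread of each probe set, and moderation draws spreads towards a common value, so these recovery rates may be too high. On the real arrays Foxo1, 6.18-fold lower at day 25 on its brightest probe set, did not pass in limma (adjusted p = 0.508). The number of arrays limits the precision. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

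Alternatives were array centring, repeated quantile normalization, a filter on dim probe sets, an intensity trend with a robust prior, fits of the 4 arrays compared, the mean of all probe sets of a gene, exclusion of cross-hybridizing probe sets, a replicate block, a 2-fold threshold, a 0.01 threshold and leaving out each array. Array weights, a pseudocount of 16, a crossed block, list tests and medians without each array, the oocyte marker level as a covariate and the FOXO list without its FOXO genes were added after seeing the data. With an array left out, the lone array of its group is assumed to vary like the other groups. Leaving out an array of the group not compared changes only the pooled spread, not the log2 differences. For the correlation of 2 contrasts that share wild type, unchanged groups were simulated 100 times.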

Results

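Granulosa cells, the somatic cells that surround and feed the oocyte in the ovarian follicle, were profiled on 6 Affymetrix mouse expression arrays in 3 groups of 2. The groups were wild type at day 25 of age, a knockout at day 25, and the same knockout at 2 months. The knockout, called dKO here, carries conditional alleles of Foxo1 and Foxo3 with a Cre driver expressed from the Amhr2 locus in granulosa cells. Foxo1 and Foxo3 encode forkhead transcription factors that are held inactive by insulin and PI3K signalling. All mice had a mixed FVB and C57BL/6 background, and 2-month wild-type cells were not analysed here. The median intensity was 73 or 74 on every array. dKO 2-month replicate 1 stood apart, with r between 0.964 and 0.979 against the other 5 arrays across probe sets, while those 5 had r between 0.982 and 0.993 with each other. In the dKO 2-month group, 1466 genes differed by over 2-fold between the replicates, against 419 in wild type and 342 in dKO at day 25.

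The targeted genes were examined first. Foxo1 intensity on its brightest probe set was 10319 and 7666 on the wild-type arrays, 904 and 2291 on the dKO arrays at day 25, and 126 and 343 on the dKO arrays at 2 months. The log2 difference from wild type was -2.63 ± 0.65 (SE) at day 25, adjusted p = 0.508, and -5.41 ± 0.65 at 2 months, adjusted p = 0.139. Although neither value passed the test, both dKO arrays at each age lay below both wild-type arrays, and the other bright Foxo1 probe sets ran the same way. The dimmest Foxo1 probe set stayed between 14 and 22 on all arrays. Foxo3 was not lower in the dKO. Its brightest probe set gave 1487 ± 205 (SD, n = 2) in wild type, 2909 ± 523 in dKO at day 25 and 2178 ± 433 at 2 months, and the log2 difference at day 25 was 0.96 ± 0.22 (SE), adjusted p = 0.485. All 3 Foxo3 probe sets had higher means in the dKO at day 25. The labels do not state which part of either gene is removed, so a Foxo3 probe set outside that part checks nothing.

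**Figure D1:**
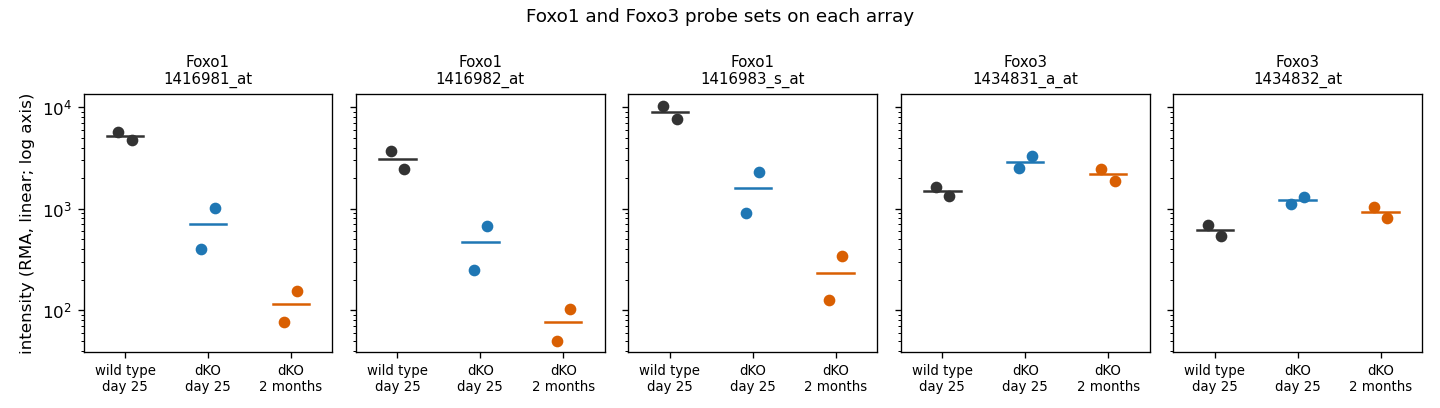
Intensity of the 5 Foxo1 and Foxo3 probe sets that exceeded 100 on any array, on a log axis, with a point per array and a bar at the group mean. The brightest Foxo1 probe set, in the third panel, runs from 10319 and 7666 in wild type to 126 and 343 in dKO at 2 months, while the brighter Foxo3 probe set is lowest on the wild-type arrays, at 1632 and 1342.

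The comparison of dKO with wild type at day 25 sets the genotypes side by side at a matched age. The dKO also carries the Cre driver at the Amhr2 locus, whose own effect was not tested. Genes that earlier work has reported as FOXO targets fell as a group, with a median log2 difference of -0.51 over 36 measured members. Camera gave the list adjusted p = 2.12e-08, against adjusted p = 0.525 with an estimated correlation. Of the 36 members, 30 had lower means in the dKO, and 14 were lower and 1 higher at an unadjusted p under 0.05. Over all probe sets 0 members passed, and adjusted over the list alone 3 passed, all lower. Irs2, an adaptor that links the insulin receptor to PI3K, was 113 ± 15.6 in dKO and 334.5 ± 0.707 in wild type (SD, n = 2), a 2.96-fold difference. Klf6, a zinc finger transcription factor, was 284.5 ± 16.3 against 599 ± 28.3. Gadd45a, which acts in growth arrest and the DNA damage response, was 493.5 ± 54.4 against 1003.5 ± 7.78. Ccnd2, the D cyclin that drives granulosa cell division, was 3787.5 ± 493 against 6420 ± 444. The list holds no expected direction for its members, so a fall such as that of Ccnd2 does not by itself speak for loss of FOXO activity. The list also contains Foxo1, Foxo3 and Foxo4 themselves. It kept its call when any 1 of the 6 arrays was left out, with adjusted p from 4.88e-08 to 2.83e-06. Oocyte markers were higher on the same arrays (median log2 difference 1.10), as were leukocyte markers (0.745, or 0.32 without wild-type replicate 1 and 0.46 without dKO day 25 replicate 1).

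Some further genes of insulin and IGF signalling had low dKO values, but the list as a whole was not called by camera (adjusted p = 0.123). Its median log2 difference was -0.02, with 12 members higher and 14 lower. This list shares Irs2 and Insr with the FOXO list, so the counts of the lists are not separate. Sgk1, a kinase downstream of PI3K, was 407.5 ± 96.9 in dKO and 1309.5 ± 149 in wild type (SD, n = 2). Igf1r, the IGF1 receptor, was 1722 ± 150 against 3278.5 ± 337, and Igfbp2, an IGF binding protein, was 1129 ± 178 against 2055 ± 12.7. Of the 26 measured members, 5 were lower and 2 higher at an unadjusted p under 0.05. Adjusted over the list alone 4 passed, all lower, and over all probe sets 0 passed. The fry test of change in either direction gave this list adjusted p = 0.00322.

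Genes of the extracellular matrix and basal lamina rose as a list in the dKO at day 25, with adjusted p = 0.035 by camera and adjusted p = 0.787 with an estimated correlation. The median log2 difference was 0.34 over 28 members, of which 7 were higher and 1 lower at an unadjusted p under 0.05. None passed adjusted over the list alone or over all probe sets. Nid2, a nidogen that joins laminin and collagen IV networks, was 1398.5 ± 856 in dKO and 173 ± 58.0 in wild type (SD, n = 2), and Nid1 was 1536.5 ± 388 against 740 ± 250. Sparc, a collagen-binding matrix protein, was 6769.5 ± 865 against 3901 ± 424, and Lamb1, a laminin chain, was 5524 ± 43.8 against 3096 ± 717. On the same arrays 16 of 16 stromal and 14 of 14 endothelial markers had higher dKO means. The call was lost without wild-type replicate 2 (adjusted p = 0.381, median 0.16), without dKO day 25 replicate 1 (0.178) and without either dKO 2-month array (0.0681 each).

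Markers of 4 other cell types were called in the same direction. Stromal and smooth muscle markers rose (adjusted p = 0.00131, median log2 difference 0.51), with 16 of 16 members higher, among them Ogn, a proteoglycan, at 4093 ± 178 in dKO and 1332.5 ± 81.3 in wild type (SD, n = 2). Endothelial markers rose (adjusted p = 0.00131, median 0.44), and Cdh5, the vascular cadherin, was 154.5 ± 17.7 against 81.5 ± 0.707. Leukocyte markers rose (adjusted p = 0.00267, median 0.745), and Lyz2, the lysozyme of myeloid cells, was 3157 ± 1600 against 887.5 ± 528. Oocyte markers rose (adjusted p = 0.00131, median 1.10), and Oosp1, an oocyte-secreted protein, was 9981.5 ± 1402 against 4970.5 ± 1189. With an estimated correlation each of these 4 lists had adjusted p = 0.787. Members higher at an unadjusted p under 0.05 numbered 3 for stroma, 4 for endothelium and 0 for both leukocytes and oocytes; over all probe sets and adjusted over the list alone, 0 passed in each. Without wild-type replicate 2 the adjusted p was 0.182 for stroma and 0.132 for oocytes, and without dKO day 25 replicate 2 it was 0.068 for each of them and 0.152 for endothelium. Without wild-type replicate 1 it was 0.126 for leukocytes and 0.0549 for endothelium, and without dKO day 25 replicate 1 it was 0.0767 for leukocytes. The medians moved as well. Without wild-type replicate 1 they were 0.32 for leukocytes and 0.23 for endothelium, and without wild-type replicate 2 the stromal median was 0.27. Without dKO day 25 replicate 1 they were 0.46 for leukocytes, 0.74 for endothelium and 0.87 for stroma, and without replicate 2 of that group the endothelial median was 0.17. With dim genes left out, the endothelial list had adjusted p = 0.233.

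**Figure D2:**
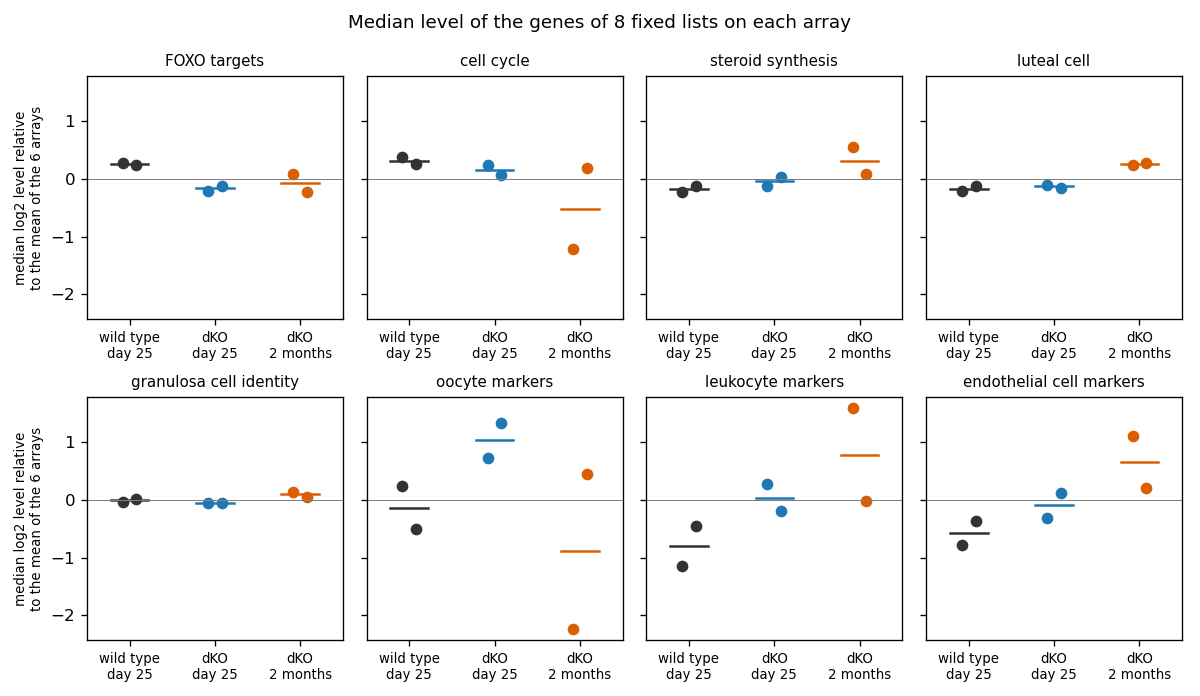
Median level of the genes of 8 lists on each array, in log2 units relative to each gene's mean over the 6 arrays, with a point per array and a bar at the group mean. FOXO targets lie at 0.27 and 0.24 in wild type and at -0.20 and -0.12 in dKO at day 25, and the cell cycle point at -1.22 and the oocyte point at -2.24 belong to dKO 2-month replicate 1.

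At the level of single genes, 0 probe sets passed an adjusted p of 0.05 in limma at day 25, and the smallest adjusted p was 0.367. At an unadjusted p under 0.05 there were 3668 probe sets, where 2252 are expected by chance. Of genes, 887 were higher and 624 lower, where chance gives 910 in both directions together. Without wild-type replicate 1 these counts were 526 and 380, without wild-type replicate 2 they were 563 and 446, and without either dKO 2-month array 1644 and 1106. Without dKO day 25 replicate 1 they were 657 and 293, and without replicate 2 of that group 565 and 478. The groups did not overlap for 45.81% of genes, where chance gives 33.33%. Among the genes with the smallest p, Steap4, a metalloreductase, was 1087 ± 48.1 in dKO and 123 ± 8.49 in wild type (SD, n = 2), a log2 difference of 3.13 ± 0.19 (SE). Mrap2, a melanocortin receptor accessory protein, was 412.5 ± 118 against 52.5 ± 6.36, Lrrc3b was 288.5 ± 98.3 against 31 ± 5.66, and Srpk3, a kinase, was 117 ± 9.90 against 37 ± 4.24. Ldb3, a protein of the muscle Z line, was 269 ± 66.5 against 29 ± 5.66. In the other direction, Mpped2 was 385.5 ± 74.2 against 1230 ± 82.0. Trim34a was 28 on both dKO arrays against 168.5 ± 16.3, with its other probe set opposite in sign, and Trim30d was 10.5 ± 0.707 against 58.5 ± 16.3. Irs2 and Klf6 completed the lower set. All 10 had adjusted p = 0.367.

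For the genes that define granulosa cells and their hormones, no difference passed at day 25. No probe set of any gene passed there, so this does not show that these genes were unchanged. Inha, the inhibin alpha subunit, was 26977 ± 738 in dKO and 26546 ± 718 in wild type (SD, n = 2), and Foxl2, the factor that maintains granulosa identity, was 7039 ± 1021 against 6474 ± 437. Amh, the anti-Müllerian hormone, was 2578.5 ± 682 against 2496 ± 601, and Fst, which binds activin, was 8965.5 ± 2191 against 9422 ± 505. The activin subunits Inhba and Inhbb had log2 differences of 0.55 ± 0.28 (SE) and 0.29 ± 0.12, and Inhba's other probe set was opposite in sign. Bmp2 had -0.66 ± 0.70, Igf1 0.32 ± 0.32 and Fshr, the FSH receptor, 0.48 ± 0.29. None of these passed, with adjusted p from 0.636 for Inhbb to 1 for Amh. Inha lay close to the highest intensity of any probe set on every array, and Inhba and Inhbb were bright too. Whether signal levels off at such intensities was not tested, so a difference in these genes, above all in Inha, could be understated. The granulosa identity list had a median of -0.06 and adjusted p = 0.428. Cyp19a1 and Lhcgr were not analysed here.

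The other lists were not called at day 25. Cell cycle (adjusted p = 0.0872), apoptosis (0.123), steroid hormone synthesis (0.262), antioxidant defence (0.262) and theca markers (0.428) were among them. So were FSH response, activin and BMP signalling, cholesterol synthesis and WNT signalling (0.428 each), surface epithelium (0.455), ovulation (0.457), luteal cell (0.59), erythrocyte (0.681), glycolysis (0.693), interferon response (0.757) and Sertoli cell (0.792). Bcl2l11, a killer of the BCL2 family that FOXO factors are reported to activate, was 606 ± 55.2 in dKO and 880 ± 36.8 in wild type (SD, n = 2), adjusted p = 0.549. For the FSH response and ovulation lists the median was above 0 while the mean and the camera direction were below 0. The exact permutation test of 2 arrays against 2 cannot give a p below 0.333.

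**Figure D3:**
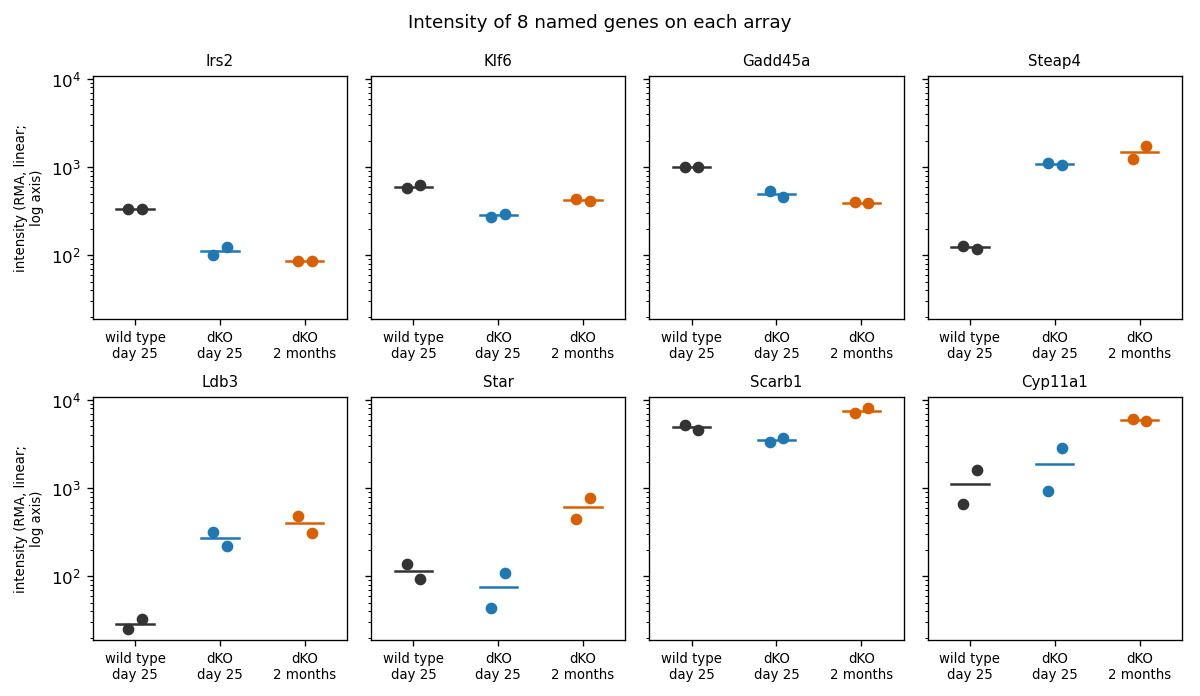
Intensity of 8 named genes on each array, on a log axis, with a point per array and a bar at the group mean. Irs2, Klf6 and Gadd45a are highest on the wild-type arrays, Steap4 and Ldb3 are lowest there, and Star, Scarb1 and Cyp11a1 are highest on the dKO 2-month arrays.

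The comparison of dKO at 2 months with dKO at day 25 follows the mutant cells with age. Genes of steroid hormone synthesis rose, with a median log2 difference of 0.735 over 15 measured members, adjusted p = 0.00103 by camera and adjusted p = 0.747 with an estimated correlation. Of its members, 7 were higher and 0 lower at an unadjusted p under 0.05. Adjusted over the list alone 4 passed, and over all probe sets 0 passed. Star, which carries cholesterol into mitochondria, was 609.5 ± 227 at 2 months and 76.5 ± 46.0 at day 25 (SD, n = 2), an 8.37-fold difference. Scarb1, the HDL receptor, was 7562 ± 748 against 3536.5 ± 257, and Fdx1, the electron donor of mitochondrial steroid enzymes, was 8017.5 ± 235 against 2975 ± 1140. Cyp11a1, which makes pregnenolone from cholesterol, was 5933.5 ± 185 against 1875 ± 1353, although its other 2 probe sets were opposite in sign. Nr5a1, a nuclear receptor that drives steroid enzyme genes, was 1550.5 ± 221 against 641.5 ± 295. The list kept its call when any 1 of the 6 arrays was left out. It did so only narrowly without dKO 2-month replicate 1, where its median was 0.29. The wild-type arrays enter this comparison only through the pooled spread. Theca and interstitial markers, which share Star, Cyp11a1 and Cyp17a1 with this list, were higher on the same arrays (median 0.575, or 0.32 and 0.865 without dKO day 25 replicates 1 and 2).

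Luteal cell genes also rose between day 25 and 2 months in the dKO (adjusted p = 0.00255, median log2 difference 0.27 over 16 members), with adjusted p = 0.747 with an estimated correlation. At an unadjusted p under 0.05, 6 were higher and 0 lower, and 5 passed adjusted over the list alone. Sfrp4, a secreted WNT antagonist of the corpus luteum, was 329.5 ± 136 at 2 months and 133 ± 14.1 at day 25 (SD, n = 2), and Star and Scarb1 belong to this list too. Ovulation and cumulus expansion genes rose (adjusted p = 0.0219, median 0.31; adjusted p = 0.747 with an estimated correlation). Ptger2, a prostaglandin receptor, was 920 ± 535 against 294.5 ± 77.1, and Egr1, an early response transcription factor, was 4956 ± 52.3 against 2641.5 ± 1152. Of 21 ovulation members, 6 were higher and 0 lower at an unadjusted p under 0.05, and 0 passed adjusted over the list alone. Over all probe sets 0 members of either list passed. Markers of other cells differed between the same arrays, with higher means for 14 of 14 endothelial, 21 of 21 leukocyte and 6 of 9 theca markers and lower means for 19 of 19 oocyte markers, and Star is a theca marker as well. Without dKO 2-month replicate 2 the adjusted p was 0.0929 for the luteal list and 0.0757 for the ovulation list, which also lost its call without either wild-type array (0.0756 each). The luteal median was 0.41 without dKO 2-month replicate 2, and the ovulation median was 0.18 without dKO day 25 replicate 2 and 0.20 without dKO 2-month replicate 1. With dim genes left out the luteal list had adjusted p = 0.0529 and the ovulation list 0.174.

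Cell cycle genes fell between day 25 and 2 months by camera (adjusted p = 1.07e-07, median log2 difference -0.66), with adjusted p = 0.773 with an estimated correlation. The fall lay on a single array. On dKO 2-month replicate 1 the median level of the list was -1.22 relative to the mean of all arrays, against 0.19 on replicate 2, and 38 of 39 members had their lowest value there. Without that array the median log2 difference was -4.73e-05 and the adjusted p 0.936, and without replicate 2 of that group the median was -1.38. With the oocyte marker level as a covariate the list turned to higher (adjusted p = 0.0188), but dKO 2-month replicate 1 is the lowest in both and sets the slope of that covariate, so the turn says nothing of its origin. No member passed at an unadjusted p under 0.05, over all probe sets or adjusted over the list alone. Bub1b, a spindle checkpoint kinase, was 1627 ± 1007 at 2 months and 3020 ± 5.66 at day 25 (SD, n = 2). Oocyte markers were lowest on the same array (median -2.24, against 0.46 on replicate 2) and leukocyte markers highest (1.59 against -0.02).

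Several marker lists and the interferon list were called in this comparison too. Oocyte markers fell (adjusted p = 5.35e-08, median log2 difference -1.88), and Figla, an oocyte transcription factor, was 104 ± 69.3 at 2 months and 313 ± 156 at day 25 (SD, n = 2). Endothelial markers rose (adjusted p = 4.47e-07, median 0.805), and Robo4 was 178.5 ± 19.1 against 78 ± 11.3. Leukocyte markers rose (0.00104, median 0.70), as did surface epithelium (0.00176, median 0.80), theca and interstitial markers (0.0129, median 0.575) and interferon response genes (0.0331, median 0.315). Among these, Cyp17a1, the androgen enzyme of theca cells, was 13916 ± 1573 against 2731 ± 3312, and Oas1a was 253.5 ± 2.12 against 194.5 ± 3.54. With an estimated correlation, adjusted p = 0.747 for the oocyte, endothelial, epithelium and theca lists and adjusted p = 0.773 for the leukocyte and interferon lists. At an unadjusted p under 0.05, 1 oocyte member was lower, and 4 endothelial, 4 theca, 1 epithelium, 1 interferon and 0 leukocyte members were higher. Over all probe sets 0 passed, and adjusted over the list alone 1 endothelial and 1 theca gene passed. Without dKO 2-month replicate 1 the interferon and leukocyte lists turned to lower (adjusted p = 0.94 and 0.872), epithelium had 0.224 and theca 0.0892. Theca had 0.115 without dKO 2-month replicate 2 and 0.0708 without dKO day 25 replicate 1, interferon had 0.099 and 0.0843 without dKO day 25 replicates 1 and 2, and leukocytes had 0.0513 without dKO day 25 replicate 2. Most of these medians rested on dKO 2-month replicate 1. Without it they were -0.60 for oocytes, 0.315 for endothelium, 0.32 for epithelium, -0.03 for leukocytes and -0.02 for interferon, and without replicate 2 of that group they were -3.20 for oocytes, 1.49 for leukocytes and 1.44 for epithelium. Without dKO day 25 replicate 1 the medians were 0.505 for endothelium, 0.32 for theca and 0.21 for interferon, and without dKO day 25 replicate 2 they were 0.36 for leukocytes and 0.865 for theca. With dim genes left out, adjusted p was 0.583 for interferon, 0.0572 for leukocytes and 0.461 for epithelium, and with the oocyte marker level as a covariate epithelium had 0.512 and the interferon and leukocyte lists turned to lower (0.0834 and 1.44e-06).

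No single probe set passed in limma between the dKO ages. The smallest adjusted p was 0.712, and 2514 probe sets had an unadjusted p under 0.05 where 2252 are expected. Of genes, 678 were higher and 528 lower, where chance gives 910 in both directions together. Without dKO 2-month replicate 2 these counts were 2322 and 2655, and without replicate 1 of that group 572 and 336. They were 319 and 398 without dKO day 25 replicate 1, 508 and 256 without dKO day 25 replicate 2, and 473 and 331 without either wild-type array. The groups did not overlap for 36.66% of genes, where chance gives 33.33%. Among the genes with the smallest p were the water channels Aqp2, at 867.5 ± 4.95 at 2 months and 145.5 ± 24.7 at day 25 (SD, n = 2), and Aqp5, at 1552 ± 222 against 237.5 ± 40.3. Niban1 was 640 ± 83.4 against 159.5 ± 34.6, Spns2, a sphingosine phosphate transporter, was 293 ± 32.5 against 96 ± 15.6, and Junb was 248 ± 7.07 against 84.5 ± 7.78. Col9a2, a collagen IX chain, was 60 ± 12.7 against 324 ± 11.3, Arnt2 was 145 ± 4.24 against 406.5 ± 79.9, and Sema4d was 160 ± 2.83 against 321.5 ± 31.8. Pdgfb was 392 ± 55.2 against 788 ± 46.7, and Ccdc68 was 342 ± 9.90 against 686 ± 60.8. The BMP-responsive genes Id1 and Id2 had log2 differences of 1.55 ± 0.44 (SE) and 1.45 ± 0.43, and Fst had -0.82 ± 0.21.

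The remaining lists were not called between the dKO ages. FOXO targets had a median of 0.13 (adjusted p = 0.542), granulosa identity 0.07 (0.542), apoptosis 0.13 (0.0679) and antioxidant defence 0.15 (0.0753). Cholesterol synthesis had adjusted p = 0.234, WNT signalling 0.617, extracellular matrix 0.668, stroma 0.829, Sertoli cell 0.917 and erythrocyte 0.983. FSH response, activin and BMP signalling, insulin signalling and glycolysis had 0.542 each. With no 2-month wild type analysed here, these differences have no measure of normal ageing beside them.

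In the comparison of dKO at 2 months with wild type at day 25, genotype and age differ together and cannot be separated. FOXO targets fell (adjusted p = 0.000533, median log2 difference -0.29; adjusted p = 0.675 with an estimated correlation), with 11 members lower and 3 higher both at an unadjusted p under 0.05 and adjusted over the list alone, and 0 over all probe sets. Irs2 was 87 on both dKO arrays against 334.5 ± 0.707 (SD, n = 2), a log2 difference of -1.93 ± 0.12 (SE), and Gadd45a was 395.5 ± 6.36 against 1003.5 ± 7.78. Among insulin and IGF genes, Igf1r was 1289.5 ± 235 against 3278.5 ± 337, and Igfbp2 was 786.5 ± 7.78 against 2055 ± 12.7. That list was not called by camera (adjusted p = 0.718), with 5 members higher and 5 lower at an unadjusted p under 0.05. Without dKO 2-month replicate 2 the FOXO list had adjusted p = 0.238, and without dKO 2-month replicate 1 its median was -0.55. Leukocyte markers were higher on the same arrays (median 1.69, or 0.88 without dKO 2-month replicate 1). The oocyte markers were at -2.24 and 0.46 on the dKO 2-month arrays and at 0.24 and -0.51 on the wild-type arrays, so only dKO 2-month replicate 1 lay below wild type.

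Steroid synthesis (adjusted p = 0.0349, median log2 difference 0.63) and luteal genes (0.0296, median 0.25) rose against wild type, each with adjusted p = 0.675 with an estimated correlation. At an unadjusted p under 0.05, 7 members of each were higher and 0 lower; adjusted over the list alone 5 and 7 passed, and over all probe sets 0. Star was 609.5 ± 227 against 116 ± 31.1 (SD, n = 2) and Fdx1 was 8017.5 ± 235 against 3795 ± 379. Theca markers rose (0.00803, median 1.58), with Enpep at 3852 ± 537 against 1107 ± 529, and cell cycle genes fell (2.25e-09, median -0.84), each with adjusted p = 0.675 with an estimated correlation. Adjusted over the list alone 4 theca genes and 0 cell cycle genes passed, and over all probe sets 0. Without dKO 2-month replicate 1 the steroid list had adjusted p = 0.274 and theca 0.0804, and without replicate 2 of that group steroid had 0.0666, luteal 0.176 and theca 0.0935. Without wild-type replicate 2 steroid had 0.0549, luteal 0.0572 and theca 0.108, and without wild-type replicate 1 steroid had 0.134. With dim genes left out luteal had 0.0781, and with the oocyte marker level as a covariate steroid had 0.0866. The cell cycle list kept its call without any 1 array, with adjusted p up to 0.0172, but its median was -0.11 without dKO 2-month replicate 1 and -1.59 without replicate 2.

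Extracellular matrix genes (adjusted p = 0.0193, median log2 difference 0.55) and 4 further marker lists rose against wild type. Endothelial markers had adjusted p = 9.26e-09 and a median of 1.37, leukocyte markers 4.94e-07 and 1.69, surface epithelium 0.00264 and 1.12, and stroma 0.00661 and 0.85. Oocyte markers fell (0.0387, median -0.71). With an estimated correlation, adjusted p = 0.913 for oocytes and 0.675 for the others. Among 14 endothelial markers 12 passed adjusted over the list alone, all higher, against 1 matrix gene and 0 in the other lists; over all probe sets 0 passed. Robo4 was 178.5 ± 19.1 against 47 ± 4.24 (SD, n = 2), C1qa, a complement gene of macrophages, was 1232.5 ± 1017.5 against 195.5 ± 70.0, and Timp3 was 2239 ± 1483.5 against 471.5 ± 112. Without wild-type replicate 2 the adjusted p was 0.528 for both matrix and stroma and 0.0571 for epithelium, and without dKO 2-month replicate 1 it was 0.405 for matrix. The medians without dKO 2-month replicate 1 were 0.74 for endothelium, 0.88 for leukocytes, 0.54 for epithelium, 0.56 for stroma and 0.27 for matrix. Epithelium had a median of 1.73 without dKO 2-month replicate 2, and matrix had 0.28 without wild-type replicate 2. The oocyte list had 0.51 without wild-type replicate 1 and 0.0653 without either dKO day 25 array, and turned to higher without dKO 2-month replicate 1 (adjusted p = 0.0555, median 0.50). Its median was -2.10 without dKO 2-month replicate 2, -0.44 without wild-type replicate 1 and -1.17 without wild-type replicate 2. With dim genes left out the oocyte list had adjusted p = 0.175 and epithelium 0.12, and with the oocyte marker level as a covariate matrix had 0.0624.

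In the same comparison 0 probe sets passed in limma, with a smallest adjusted p of 0.114, and 5900 had an unadjusted p under 0.05 where 2252 are expected. Of genes, 1733 were higher and 976 lower, where chance gives 910 in both directions together. Without wild-type replicate 1 these counts were 774 and 498, without wild-type replicate 2 they were 1074 and 637, and without dKO 2-month replicate 2 they were 2832 and 2628. The groups did not overlap for 43.79% of genes, where chance gives 33.33%. Steap4 was 1498.5 ± 353 in dKO and 123 ± 8.49 in wild type (SD, n = 2), and Mrap2 was 556 ± 5.66 against 52.5 ± 6.36. Hoxd8, a homeobox gene, was 977 ± 97.6 against 206.5 ± 33.2, Niban1 was 640 ± 83.4 against 105.5 ± 6.36, and Jph1, a junctophilin, was 316 ± 19.8 against 81.5 ± 14.8. Mpped2 was 225.5 ± 0.707 against 1230 ± 82.0, Col9a2 was 60 ± 12.7 against 442 ± 67.9, Arnt2 was 145 ± 4.24 against 734.5 ± 33.2, and Plch1, a phospholipase C, was 30 ± 5.66 against 156.5 ± 14.8. These genes had adjusted p = 0.123. The lists not called were cholesterol synthesis (adjusted p = 0.0741), WNT signalling (0.198), interferon response (0.202), FSH response (0.319), ovulation (0.339), insulin signalling (0.718), antioxidant defence (0.921), activin and BMP signalling and glycolysis (0.926 each), granulosa identity and Sertoli cell (0.957 each), apoptosis (0.965) and erythrocyte (0.993).

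The dKO differences from wild type at the 2 ages were then set against each other. Across 18193 genes, which are not independent replicates, the log2 differences had a correlation of 0.569. Simulated unchanged groups that shared a simulated wild type gave a mean of 0.501, with a range of 0.451 to 0.534 over 100 draws. The simulated noise was independent between genes, while members of some lists varied together on the arrays, so this range may be too narrow. Each gene had the same pooled spread in all simulated groups, which fixes where the mean falls. On the arrays 1466 genes differed over 2-fold between the dKO 2-month replicates, against 419 in wild type. The simulated correlation and covariance may therefore be too high. The covariance was 0.110 against a simulated 0.0484, a difference of 0.0618. With a different wild-type array on each side the correlation was 0.493 or 0.214. The 2 wild-type arrays cannot be split with 2 on each side, so part of any excess may come from the shared controls. The correlation was 0.763 without dKO 2-month replicate 1 and 0.331 without replicate 2.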

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

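Array weights, the pseudocount of 16, the crossed block, list tests and medians without each array, the oocyte covariate and the shortened FOXO list were chosen after seeing the data. With limma, 0 genes passed in every one of the 19 settings. The smallest adjusted p ranged from 0.14 (array weights) to 0.87 at day 25, from 0.122 (without dKO 2-month replicate 2) to 0.894 between the dKO ages, and from 0.0598 (filter on dim probe sets) to 0.735 for dKO at 2 months against wild type. Chance gives 910 genes at an unadjusted p under 0.05, both directions together. At this threshold the day 25 comparison gave 887 genes higher and 624 lower, array weights gave 1517 and 1035, and the 4 arrays compared gave 1644 and 1106. Between the dKO ages the 678 and 528 became 2322 and 2655 without dKO 2-month replicate 2, and 675 and 1230 with the crossed block. Against wild type the 1733 and 976 of dKO at 2 months became 774 and 498 without wild-type replicate 1, and 2832 and 2628 without dKO 2-month replicate 2. Of 4040 recomputed values of named genes, 419 moved by over 1 SE, 44 took the other sign and 0 passed. Of 299 recomputed list calls, 182 were kept, 110 lost and 7 reversed; where no cause is named, the cause was not tested.

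With an estimated correlation and with fry, 0 lists were called in each comparison, against 6, 10 and 11; the estimate is high for lists whose members vary together, reaching 0.915 for cell cycle. Between the dKO ages the filter on dim genes left 5 lists of 10. Leaving out an array gave 4 to 6 lists at day 25, 5 to 9 between the dKO ages (5 without dKO 2-month replicate 1) and 7 to 10 for dKO at 2 months against wild type (7 without that array or without wild-type replicate 2). With the oocyte marker level as a covariate, the oocyte list at day 25 turned to lower by camera (adjusted p = 0.812). The loss of its call follows by construction, because the covariate is that list's own median, and the sign that remains tells nothing. Between the dKO ages this covariate turned cell cycle to higher (0.0188) and interferon (0.0834) and leukocyte (1.44e-06) lists to lower. In these 3 lists dKO 2-month replicate 1, the lowest in oocyte markers, is also the extreme array and sets the slope, so these turns do not tell the origin of the difference. Leaving out an array gave the interferon list adjusted p from 0.0052 to 0.94 and the leukocyte list 2.31e-07 to 0.872 between the dKO ages, and the oocyte list 9.15e-07 to 0.51 against wild type. Without dKO 2-month replicate 1 these 3 reversed (0.94, 0.872 and 0.0555).

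Foxo1 kept its sign throughout. Leaving out an array gave log2 differences of -3.30 to -1.96 at day 25, -3.50 to -2.07 between the dKO ages and -6.13 to -4.69 for dKO at 2 months against wild type. The mean of all Foxo1 probe sets, which includes the dim one, gave -2.00 and -4.12 for the latter 2. The correlation of the dKO differences ranged from 0.331 to 0.763 when an array was left out.

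The replicate numbers did not pair the arrays, since same-numbered arrays had deviations correlated at -0.159, -0.208 and 0.0569. The fit with a replicate block called 0 genes and 5, 10 and 11 lists, and the loss at day 25 was the extracellular matrix list (0.072). The block with wild-type numbers crossed called 0 genes. The 2-fold and 0.01 thresholds had nothing to act on.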

Other observations

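The striated, skeletal and smooth muscle, Hox and immediate early groups, the single genes and the tests of explanations in this part were chosen after the values were seen, except the test of the FOXO list with the oocyte marker level as a covariate, which was set before its result was seen, while the other lists and their camera tests were planned. Some genes of the striated muscle contractile apparatus had high values in dKO granulosa cells at day 25, with 15 of 40 measured members higher and 1 lower at an unadjusted p under 0.05. The median log2 difference of the group was 0.41. Other members stayed dim on all arrays, such as Myl2 at 20 to 22 and Nppa at 13 or 14. Tnnc1, a calcium-binding troponin, was 2978 ± 1600 in dKO and 167 ± 4.24 in wild type (SD, n = 2), Tnnt2 was 252 ± 181 against 20.5 ± 7.78, and Myom1, a protein of the sarcomere M band, was 459 ± 91.9 against 89.5 ± 2.12. Pln, a regulator of the calcium pump, was 272 ± 84.9 against 69.5 ± 20.5, while Mybpc3 ran the other way, at 209.5 ± 37.5 against 661.5 ± 271. Clustered Hox genes had 8 of 26 members higher and 0 lower at an unadjusted p under 0.05. Among them Hoxd9 was 455 ± 58.0 against 209.5 ± 17.7 and Hoxc8 was 411 ± 148 against 148.5 ± 4.95. Markers of other cells were higher in the same comparison, with higher dKO means for 16 of 16 stromal and 14 of 14 endothelial markers, and the cell of origin of the Hox signal was not tested. No gene of these groups passed over all probe sets.

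Immediate early genes, which answer growth and stress signals within minutes, had a median log2 difference of 0.915 between 2 months and day 25 in the dKO. At an unadjusted p under 0.05 in limma, 10 of 20 members were higher at 2 months and 0 lower. Among the rest Myc ran the other way, at 235 and 488 on the 2-month arrays against 547 and 711 at day 25. Jun was 1981.5 ± 165 against 536 ± 161 (SD, n = 2), Btg2 was 1738 ± 124 against 718.5 ± 144, and Ier2 was 920 ± 190 against 377 ± 56.6. Between these ages 14 of 14 endothelial and 21 of 21 leukocyte markers had higher means and 19 of 19 oocyte markers lower means, and the cell of origin of the immediate early signal was not tested. Hsd17b3, an enzyme that makes testosterone, was 945.5 ± 192 at 2 months, 141.5 ± 0.707 at day 25 and 54 ± 35.4 in wild type. Stc1, a secreted glycoprotein, was 4955.5 ± 4042.5 in dKO at day 25 and 200 ± 48.1 in wild type. Bcat1, a branched-chain amino acid transaminase, was 3715 ± 1227.5 in wild type, 751 ± 232 in dKO at day 25 and 351 ± 39.6 at 2 months. All had adjusted p above 0.05 over all probe sets.

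The FOXO target list was lower in dKO at day 25 with a median of -0.51. Intervals here and below are 95% bootstrap intervals from 10000 resamples of the list members. They treat members as independent and leave out the variation between arrays. The FOXO genes in the list are argued against as its carriers, since without Foxo1, Foxo3 and Foxo4 camera gave an unadjusted p = 9.75e-10, against 8.84e-10 for the full list. With an estimated correlation the unadjusted p was 0.0216 without them and 0.0219 for the full list, which at adjusted p = 0.525 was not called. A difference in oocyte RNA stays open: with the oocyte marker level as a covariate the median was -0.301 (interval -0.526 to -0.166), but dKO 2-month replicate 1 sets the slope of that covariate, so this decides nothing. Dilution of granulosa cells by other cells also stays open, because the list lay -0.451 below the granulosa identity list with an interval of -0.673 to -0.0804, and so does loss of FOXO1 and FOXO3, the difference the design names.

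The cell cycle list was lower by -1.39 on dKO 2-month replicate 1 than on replicate 2. Degraded RNA is argued against by the ratio of 3' to 5' Actb probe sets. It was 1.67 on that array and 1.61 to 1.84 on the others. A lower share of granulosa cells stays open. The granulosa identity list was 0.189 higher on that array (interval -0.323 to 0.426), but markers of several other cells were higher there too. Their medians were 1.59 for leukocytes, 1.11 for endothelium and 1.285 for surface epithelium, against -0.02, 0.21 and 0.11 on replicate 2. Less oocyte RNA may be the source and stays open, as oocyte markers differed by -2.65 between the same arrays. In the other groups the replicate with more oocyte signal (by 0.668) had a cell cycle median of -0.0437 relative to its partner (interval -0.114 to 0.0368), but the groups went opposite ways, 0.08 in wild type and -0.17 in dKO at day 25, so this decides nothing. A different state of the follicles in that sample stays open too and was not tested.

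The striated muscle genes may come from other cells. Skeletal muscle tissue is argued against, because its abundant genes had a median log2 difference of 0.0397 (interval -0.0674 to 0.232) and none exceeded 0.793. Smooth muscle cells stay open: between the dKO 2-month replicates, where smooth muscle markers differed by 0.388, the 15 striated genes that were higher at an unadjusted p under 0.05 at day 25 differed by -0.0473, with a wide interval of -0.128 to 0.643. Expression in the mutant granulosa cells themselves stays open and untested.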
